A study of Mus musculus with 6 samples.

How the data were processed

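RNA was measured in C2C12 cells, a mouse myoblast line that can form muscle or osteoblasts. Per the labels, 3 samples were grown for 2 days in medium with 1% DMSO, the solvent, and 3 in medium with 10 µM of a hit from a high-throughput screen, a dimethylquinolinone that carries a phenylimidazole group, here called the compound. Cells grew in 12-well plates, and 100 ng of Trizol RNA per sample entered a poly-A library. The labels name the TruSeq RNA kit v2 and also call the library stranded. The submitters' processing notes list STAR 2.3.0e, HTSeq 0.6.0 and the mm10 build. The strand setting of the counting and the annotation release are not given in the sources used here.

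The authors deposited 1 table of 24725 rows. It held 22753 gene identifiers, because 930 identifiers stood in more than 1 row with equal counts; each was used once. All were protein-coding genes except 13 polymorphic pseudogenes. Raw read counts per gene and library, as deposited by the authors, were the input to every test. The table also held a normalised signal, which per the file headers and values was the deposited count divided by 1 size factor per library. The authors' DESeq2 log2 fold changes, their Wald score and the deposited p-values are per the file headers and were used only for the totals and genes attributed to the authors' deposited table.

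Genes were placed on mm10 with GENCODE M21, which held 21854 (96.0%) of the identifiers. For each gene, exons of other genes on the opposite strand were intersected with its own exons. The overlapping gene is named beside the most changed genes, because without a stated strand setting the reads of such a pair cannot be told apart. As a comparison chosen after the data were seen, counts were also summed by opposite-strand gene. This sum used the 2100 table genes with exactly 1 gene on the opposite strand overlapping their exons, protein-coding and by at least 50 bp, and gave 2005 opposite-strand genes.

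Differential counts were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr by group, quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment at 0.05. This left 2440 genes, and 1034 opposite-strand genes. Standard errors are the absolute log2 fold change divided by the square root of F. Levels are CPM, counts scaled to the TMM library size over the tested genes, as mean ± SD with n = 3. Gene lists, 52 in all, were fixed before the data were examined and tested with camera of limma 3.58.1 (prior count 2, preset correlation 0.01). By the table's gene names a list needed 5 tested members, which 14 lists had; by opposite-strand gene it needed 3, which 7 had. Nothing in the labels says that the samples were separate cultures, so p-values measure the spread between these samples, which may be technical.

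The genes named by rule were the 10 largest rises and 10 largest falls with adjusted p under 0.05, mean count of at least 50 and groups that do not overlap, leaving out predicted or clone names. The rule added the 5 smallest p-values, up to 4 members per list past the threshold with mean count of at least 20, else its 2 highest-count members, and 14 genes fixed in advance. Opposite-strand genes were named with the first part of the same rule and by list membership. For lists with fewer than 5 tested members, the highest-count members are given only as a range. Some genes that the rule selects are not reported here.

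The steps were checked on simulated counts for the compound against DMSO comparison. Of 2290 simulated genes tested, 48.4% of those changed 2-fold and 95.5% of those changed 4-fold were recovered, and 5 of 135 calls were false. Alternatives were DESeq2 1.42.0 and its size factors, upper-quartile scaling, limma-voom, no filter, a mean count of at least 50, a replicate block, each library left out in turn, an adjusted p of 0.01, estimated correlation, fry and a prior count of 0.5. Permutation tests and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Total counts ran from 493406 to 952813 per library. They cover protein-coding genes of the table only, so they are part of each library and not its depth. A count of 0 allows up to 3 counts, or 3.15 to 6.08 CPM of the library total; this limit covers counting error only and does not bound the level of a transcript whose reads were not counted under its gene.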

Results

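Poly-A RNA of C2C12 myoblasts was counted per gene in 3 DMSO samples and 3 samples treated for 2 days with 10 µM of the compound. The comparison asks how this screening hit alters the transcripts of a cell that can become muscle or bone. Totals were 566348, 597112 and 952813 counts in DMSO replicates 1 to 3. In the compound group they were 493406, 515296 and 542649. Between 6981 and 9522 genes had a count in a library. Every pair of libraries differed by more than counting noise. Within DMSO, replicates 1 and 2 lay closest (chi-square per degree of freedom 1.88), whereas replicate 3 stood at 10.5 and 9.60 from them. Compound libraries differed among themselves by 2.64 to 2.83. This measure grows with the total count: correlations of log2 CPM within DMSO were 0.951 to 0.975 and within the compound group 0.950 to 0.956, and compound replicate 1 lay as far out on the second principal component (13.6) as DMSO replicate 3 (12.0).

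The counts were unevenly placed on the genome, and this bears on every gene named here. Genes whose exons are overlapped by exons of an opposite-strand gene made up 5348 (23.5%) of the table and held 91.82% of all counts. The 13775 genes without a gene on the opposite strand held 5.35%. Transcripts abundant in most cells had few counts: Actb, cytoplasmic actin, had a mean count of 8.17, Gapdh 20.7 and Rpl3 0.167. Among mitochondrial genes, mt-Nd6, the protein-coding gene of the light strand, had the highest count, 26553 to 57919 per library, while mt-Co2, mt-Co3 and mt-Atp6 had 0. Changes are therefore given as changes of the counts filed under a gene, with the opposite-strand neighbour of the most changed genes named.

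**Figure D1:**
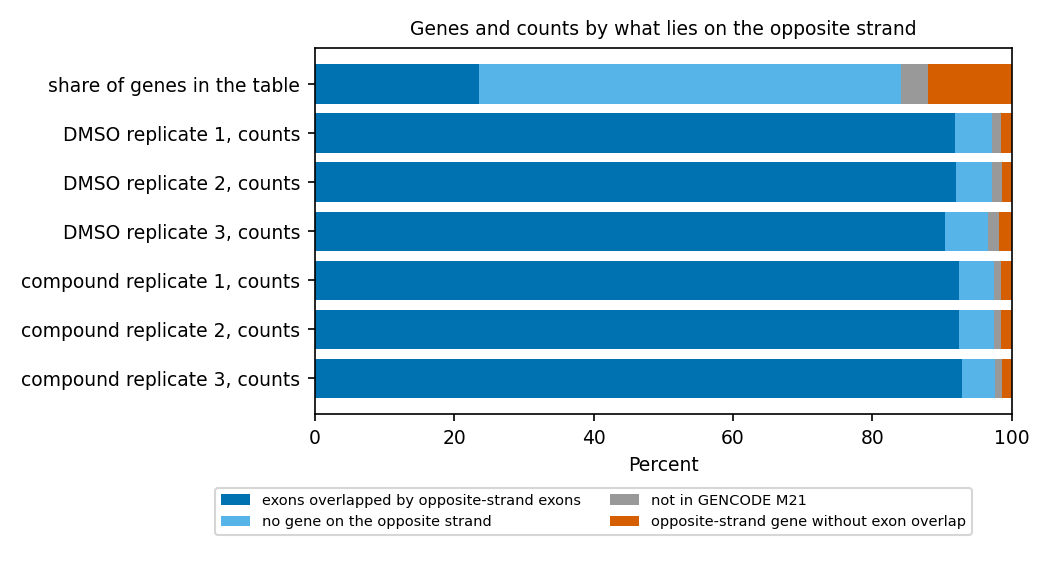
Percent of genes in the table (top bar) and percent of counts in each of the 6 libraries (other bars), split by what the annotation holds on the opposite strand. Genes with opposite-strand exon overlap make up 23.5% of the table and between 90.47% and 92.83% of the counts.

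The compound changed counts filed under 438 of 2440 tested genes, 183 higher and 255 lower, and 102 of the rises and 160 of the falls were at least 2-fold. Among genes with a mean count of at least 50, the sharpest rise was under Idua, a lysosomal iduronidase gene, from 83.8 ± 8.76 to 1713 ± 150 CPM (SD, n = 3), or 20.5-fold. The sharpest fall among them was under Copg2, a coatomer subunit gene, from 1308 ± 163 to 80.9 ± 4.04 CPM, or 16.1-fold lower. Counts filed under Ctsa, which encodes the lysosomal protease cathepsin A and is overlapped by Pltp and Neurl2, rose 5.98-fold to 10768 ± 347 CPM. The compound and DMSO libraries separated on the first principal component, which carried 52.99% of the variance. DMSO and compound libraries did not overlap in 36.4% of tested genes, where chance gives 10%. The authors' deposited table, from DESeq2, listed 244 genes higher and 351 lower among 4542 with an adjusted p. Without compound replicate 1 there were 93 higher and 143 lower, without compound replicate 2 103 and 151, without compound replicate 3 109 higher, and without DMSO replicate 2 114 higher. Without DMSO replicate 3 there were 259 higher and 359 lower.

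Among the largest rises, Idua (chromosome 5, 108660331 to 108684557, plus strand) changed by 4.36 ± 0.18 (log2, SE) with an adjusted p of 3.11e-10 in edgeR's quasi-likelihood test. Its exons are overlapped by those of Slc26a1 and Dgkq on the minus strand. Zswim1, overlapped by Spata25, rose 17.1-fold from 16.7 ± 3.01 CPM. Aven, an apoptosis inhibitor gene overlapped by the calcium channel gene Ryr3, rose 3.91-fold. Syn3, a synapsin gene whose exons overlap 1733 bp of the metalloprotease inhibitor gene Timp3, rose 3.55-fold to 17027 ± 414 CPM. Pfkp, a phosphofructokinase gene overlapped by Pitrm1, rose 3.47-fold. Hectd2 rose 3.70-fold, Spon1 2.87-fold and Tstd2 2.70-fold; Hectd2 is overlapped by Hectd2os, Tstd2 by Tmod1 and Ncbp1, and Spon1 by none annotated. Gm9817, a predicted gene overlapped by the pseudogene Hsp25-ps1, was among the 5 smallest p-values and rose 2.71-fold to 43360 ± 1132 CPM.

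Among the largest falls, Copg2 (chromosome 6, 30747554 to 30896794, minus strand) changed by -4.01 ± 0.19 (log2, SE) with an adjusted p of 8.49e-10 in edgeR. Its exons overlap 912 bp, from 30747554 to 30748465, of Mest, an imprinted gene of mesoderm. Hdgfrp3, overlapped over 1220 bp by Tm6sf1, was 13.8-fold lower. Noc4l, a ribosome biogenesis gene with no annotated opposite-strand exon, was 11.5-fold lower. Zyx, the gene of the focal adhesion protein zyxin, was 7.14-fold lower and is overlapped by Epha1. Cerkl, overlapped by the integrin gene Itga4, was 5.68-fold lower, and Hps3, overlapped by the ceruloplasmin gene Cp, 4.97-fold lower. Paqr4 is overlapped by Pkmyt1, a kinase that restrains entry into mitosis, and was 4.71-fold lower. Clcn1, the muscle chloride channel gene overlapped by Fam131b, was 4.71-fold lower too, and Ccdc24, overlapped by the glycine transporter gene Slc6a9, 4.61-fold.

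**Figure D2:**
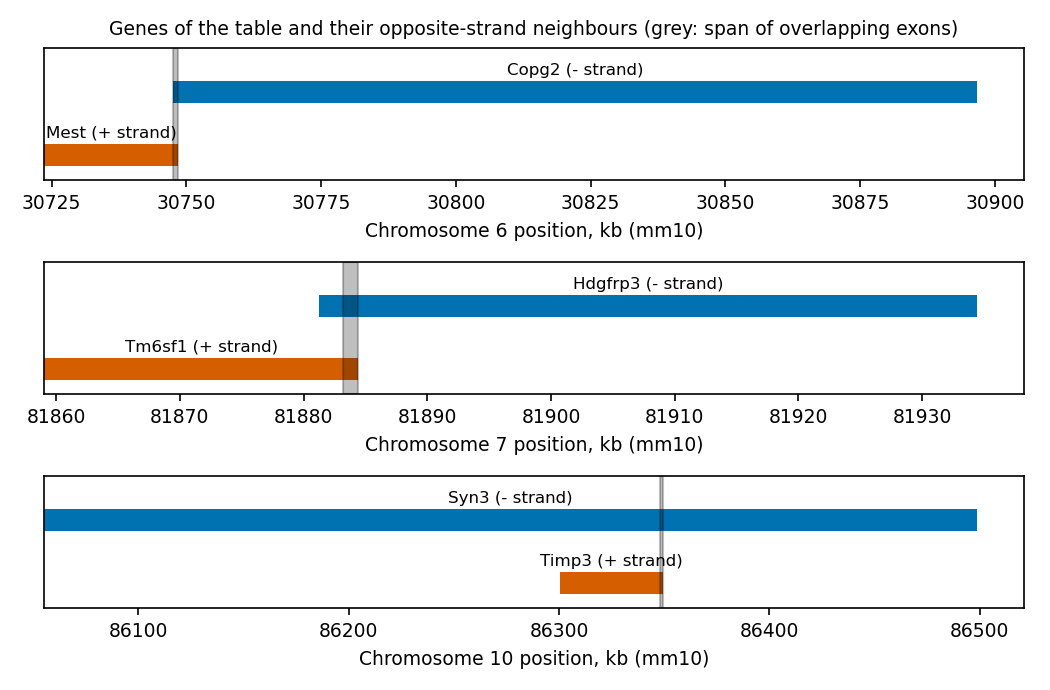
Position in kb of 3 genes of the table (blue) and of their opposite-strand neighbours (orange), with the span of the overlapping exons in grey. The overlap covers 912 bp for Copg2 and Mest, 1220 bp for Hdgfrp3 and Tm6sf1, and 1733 bp for Syn3 and Timp3.

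By the table's own gene names, none of the 14 tested lists passed camera. At an unadjusted p under 0.05, 1 list did, lysosome genes (adjusted p = 0.213), and the other 13 lists had adjusted p from 0.634 to 0.975. Of the tested lysosome members, 4 rose: Ctsa, Npc1, a cholesterol transporter gene, 2.04-fold, and, named after their values were seen, Neu1, a sialidase gene, by 2.27 ± 0.58 and Psap, the prosaposin gene, by 1.77 ± 0.48 (log2, SE). Neu1 and Psap had mean counts of only 6.83 and 11.2, under the 20 that the naming rule asks. In DMSO they stood at 4.21 and 9.71 CPM. Adjusted over the list alone, 4 lysosome members were higher and 1 lower, 4 mitochondrially encoded members higher and 2 lower, 2 growth factor members higher and 2 lower, and 2 SRF and actin members higher and 1 lower; the other lists gave the same counts as over all genes. Fry called 4 lists: lysosome (adjusted p = 0.00300), DNA replication (0.0172), and Myc targets and myogenic regulators (both 0.0292). Fry asks whether a list's members move on balance one way, not whether they differ from other genes. Among myogenic regulators, Msc, a repressor of myogenesis named after its value was seen, was lower by a log2 change of -1.21 ± 0.40, and Des, the muscle intermediate filament gene, was 1.99-fold higher. Of 7 mitochondrially encoded genes, mt-Nd6 rose 2.75-fold, mt-Cytb rose 2.21-fold and mt-Nd5, which overlaps mt-Nd6 by 14 bp, was 1.42-fold lower. The share of counts under mt-Nd6 was 2.92% to 4.83% in DMSO and 8.54% to 10.67% in the compound group. Over the 14 lists, 10 memberships were higher and 8 lower among 94. None of the tested ribosomal, collagen, unfolded protein response or respiratory chain members passed; Rpl32 and Rpl18 had log2 changes of 0.59 and 0.06, Fn1 and Col1a2 of 0.56 and -0.60, Manf and Hsp90b1 of -0.29 and -0.08, Atp5f1 of -0.18 and Cox6c of less than 0.01 in size. Without DMSO replicate 3, Rpl32 passed with 0.72 (adjusted p = 0.00238) and Col1a2 with -0.88 (0.0322). Nor did any of 9 skeletal muscle or 7 replication members, with Atp2a1 at 0.10, Tnnt2 at -0.36, Gins2 at -0.36 and Ccne2 at 0.28. The camera direction was up for skeletal muscle and unfolded protein response genes, while their median log2 changes were -0.22 and -0.01. The call of Des was lost without DMSO replicate 2, compound replicate 1 or compound replicate 2 (adjusted p up to 0.0852). That of mt-Nd5 was lost without any single compound library (up to 0.128), and without DMSO replicate 3 its log2 change was -0.31.

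Single members of other lists passed the threshold. Rises were seen under Fdft1, the squalene synthase gene, overlapped by Ctsb (log2 change 1.20), the acetyl-CoA synthetase gene Acss2 (1.72-fold) and the cystine transporter gene Slc7a11 (1.65-fold). Others were under Hsp90ab1 (2.03-fold), G6pdx, overlapped by Ikbkg (2.59-fold), Tpm2 (log2 change 1.20) and Timp2 (2.88-fold). The sum opposite G6pdx, which holds the counts under Ikbkg and is named after its value was seen, went the other way. Its log2 change was -1.20 ± 0.24 (SE, adjusted p = 0.00368 in edgeR). Which of these values follows the G6pdx transcript was not tested. Falls were seen under Ltbp2 (4.01-fold), Fosl1 (3.01-fold), Igf2r (2.61-fold), Acadvl (2.23-fold), Atf5 (2.17-fold), Pdgfa (2.03-fold), Ube2c (1.82-fold) and Nr1d1 (1.46-fold). Of these genes, Acss2 is overlapped by Gss, Acss2os and Ggt7, Ltbp2 by D030025P21Rik, Fosl1 by Ccdc85b and Acadvl by Dvl2. Atf5 is overlapped by Il4i1 and Nup62, Pdgfa by 6330403L08Rik, Ube2c by Tnnc2 and Nr1d1 by Thra. Slc7a11, Hsp90ab1, Tpm2, Timp2 and Igf2r had no annotated opposite-strand exon. Without compound replicate 1 the calls of Acss2, Slc7a11, Hsp90ab1, Ube2c, Tpm2, Fosl1, Igf2r, Pdgfa and Nr1d1 were lost. Without compound replicate 2 those of Slc7a11, Hsp90ab1, Ube2c, Tpm2, Igf2r and Nr1d1 were lost, and without compound replicate 3 those of Slc7a11, Fosl1, Igf2r, Pdgfa and Nr1d1 (adjusted p of these up to 0.158). Nr1d1 was also lost without DMSO replicate 1 or 2. Without DMSO replicate 3 the log2 change of Slc7a11 was 0.45, and that of Igf2r was -0.65 with an adjusted p of 0.375; Igf2r also missed the threshold with the other scalings, the replicate block, DESeq2 and limma-voom. The 38 lists with fewer than 5 tested members held 63 tested memberships, 7 higher and 9 lower, and 9 of them had none. Their highest-count members had mean counts of 0.833 to 302.5.

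Of the 14 genes fixed in advance, 10 had too few counts to test. Cyp1a1, the classical target of the aryl hydrocarbon receptor, had 0 counts in all 6 libraries; this sets no bound on its transcript, since mt-Co2 and mt-Co3 stood at 0 in this table too. Its relative Cyp1b1 had a log2 change of 0.37 ± 0.44 (SE, adjusted p = 0.615 in edgeR). Myod1, the myoblast determination factor, had 6, 6 and 25 counts in DMSO replicates 1 to 3 and 2, 3 and 3 with the compound, and Myog 2, 2 and 7 against 1, 0 and 0. Tiparp, Ahrr, Id1, Alpl, Utrn and Cdkn1a had mean counts of 0.167 to 4.33, and changes under these names were not tested. The sum opposite Tiparp, with a mean count of 57.2, had a log2 change of 0.05 ± 0.29 (SE, adjusted p = 0.925 in edgeR). Embryonic myosin Myh3 had a log2 change of 0.31 ± 0.38 and the osteoblast factor Runx2 of 0.01 ± 0.33, with adjusted p of 0.640 and 0.986. Ddit3, a stress response factor, stood at -0.51 ± 0.17 with an adjusted p of 0.0570, and passed without DMSO replicate 1 (0.0486), without DMSO replicate 3 (0.0418) and with a mean count of at least 50 (0.0462).

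Summed by opposite-strand gene, a comparison chosen after the data were seen, 96 of 1034 genes were higher and 142 lower with the compound. The sum opposite Mest fell 15.6-fold, from 2116 ± 211 to 135 ± 7.30 CPM, and that opposite Tm6sf1 13.4-fold. Sums opposite Timp3, an inhibitor of matrix proteases, rose 3.67-fold to 28497 ± 858 CPM, and opposite Irs1, the insulin receptor substrate, 3.11-fold to 26318 ± 971 CPM. Further rises were opposite Spata25 (17.5-fold), Tmem140 (4.42-fold), Ryr3 (4.02-fold), Pitrm1 (3.60-fold), Lcorl (2.76-fold), Ikbkg (2.68-fold), Ggact (2.67-fold) and Tuba4a (2.57-fold). Further falls were opposite Epha1 (6.90-fold), Itga4 (5.52-fold), Cp (4.83-fold), Fam131b (4.58-fold), Pkmyt1 (4.57-fold), Slc6a9 (4.49-fold), Tap2 (4.34-fold) and Dgkz (4.30-fold). These sums are not shown to measure the opposite-strand gene itself. Only 31 of the tested sums joined more than 1 tested table gene, so most repeat the counts of 1 table gene. The sum opposite Timp3 holds the counts under Syn3, that opposite Tnnc2 those under Ube2c, and that opposite Ctsb those under Fdft1. Their CPM differ because scaling was over the tested sums, and their changes are not a second measurement. Over 43 pairs of tested table genes with the same single opposite-strand gene, the log2 changes correlated with Pearson r = 0.21 (Spearman rho = 0.263, permutation p = 0.1729, across genes, which are not independent replicates). These pairs took neighbours of any type and overlap. Over 31 pairs that met the rule of the sums, chosen after the first result was seen, r was 0.416 (permutation p = 0.021). Few shuffled pairings reached this r in size, though it lay under the highest of 10000 (0.603). Without DMSO replicate 3 there were 162 higher, without compound replicate 2 59 higher, without compound replicate 1 89 lower and without compound replicate 3 90 lower.

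Of 7 lists tested by opposite-strand gene, camera called 3, and with an estimated correlation it called none. Among the other splits of the 6 libraries into 3 and 3, the highest number of lists called was 4. As many list calls can thus arise without the real grouping. Sums opposite all 3 tested mitosis genes were lower (adjusted p = 0.0109, and adjusted p = 0.161 with an estimated correlation): Ccna2, the mitotic cyclin A2, 3.50-fold, Cdc20, an activator of the anaphase-promoting complex, 5.44-fold, and Kif20a, a kinesin of cell division, 2.20-fold. The Cdc20 sum had a mean count of only 14.7 and rests on an overlap of 53 bp, just over the minimum of 50 bp. Opposite lysosome genes, 3 of 4 were higher (adjusted p = 0.0109, and adjusted p = 0.161 with an estimated correlation): Ctsb 2.37-fold, Npc1 1.86-fold and Ctsa 1.54-fold, while Sqstm1 had a log2 change of 0.12 ± 0.38. The Ctsa sum joins the counts under Pltp and Neurl2, whose log2 changes differed in sign (0.73 and -0.34). Opposite skeletal muscle genes, 5 of 6 were lower (adjusted p = 0.0282, and adjusted p = 0.295 with an estimated correlation): Ckm, muscle creatine kinase, 2.69-fold, Tnnc2 1.75-fold, Myh7 1.62-fold, Atp2a1 1.58-fold and Mybph 1.47-fold, with Myom1 at a log2 change of 0.74 ± 0.63. Adjusted over the list alone, the counts of members were the same 3, 3 and 5. Opposite DNA replication genes, Chaf1a was 2.43-fold and Ccne2 2.64-fold lower, Mcm7 and Rfc4 had log2 changes of -0.39 and -0.11, and the list did not pass (adjusted p = 0.113). Respiratory chain, proteasome and cyclin-dependent kinase inhibitor lists did not pass either (adjusted p = 0.288, 0.717 and 0.790). Without DMSO replicate 1 the muscle list missed the threshold (adjusted p = 0.0835), without DMSO replicate 3 the replication list passed (0.0216), with Mcm7 at -0.67 (0.00821), and without compound replicate 3 the respiratory chain list passed (0.0352). With no filter on low counts the muscle and lysosome lists missed the threshold (adjusted p = 0.0824 for each), and with fry the replication list passed (0.0418). Of the muscle members, Myh7 was lost without DMSO replicate 1, compound replicate 2 or compound replicate 3, Tnnc2 without DMSO replicate 2 or compound replicate 3, and Mybph without compound replicate 3 (adjusted p up to 0.101). Ccne2 was lost without DMSO replicate 1, DMSO replicate 2, compound replicate 2 or compound replicate 3 (up to 0.110). With limma-voom Tnnc2 (0.0522) and Ccne2 (0.0578) missed the threshold.

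**Figure D3:**
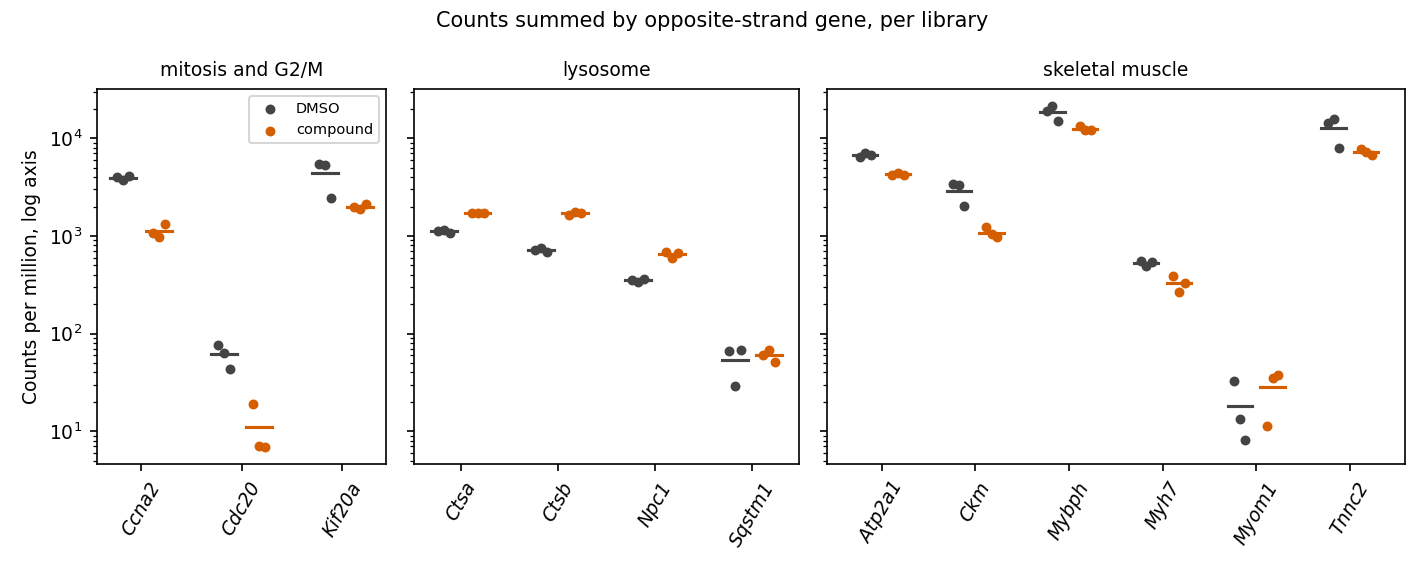
CPM (log axis) summed by opposite-strand gene for the tested members of 3 lists, with 1 point per library and a bar at the mean of the 3 libraries of a group. Ccna2 lies at 3942 ± 199 in DMSO and 1125 ± 170 with the compound (SD), and Ctsb at 719 ± 32.6 and 1704 ± 51.8.

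DMSO replicate 3 differed from the other DMSO libraries along transcript length. Over 501 genes with a mean count of at least 100 and a single protein-coding opposite-strand gene, its log2 count ratio to the mean of the other DMSO libraries had Spearman rho = 0.370 with the transcript length of that opposite-strand gene (permutation p = 1e-05, the smallest 100000 permutations can give, across genes). The median log2 ratio was 0.47 over the 167 genes with the shortest and 0.93 over the 167 with the longest opposite-strand transcripts. Summed by opposite-strand gene, Tnnc2 of the muscle list and Kif20a of the mitosis list stood at 12640 ± 4175 and 4395 ± 1707 CPM in DMSO (SD, n = 3). In DMSO replicate 3 both lay near the compound libraries. Their log2 ratios were -0.18 for Tnnc2, with a transcript of 700 bp, and -0.40 for Kif20a, with 3674 bp. Whether length accounts for these values was not tested. Tnnc2 stood at 14294, 15735 and 7891 CPM in DMSO replicates 1 to 3, against 6698 to 7720 with the compound. Kif20a stood at 5469, 5290 and 2427 CPM, against 1870 to 2128.

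**Figure D4:**
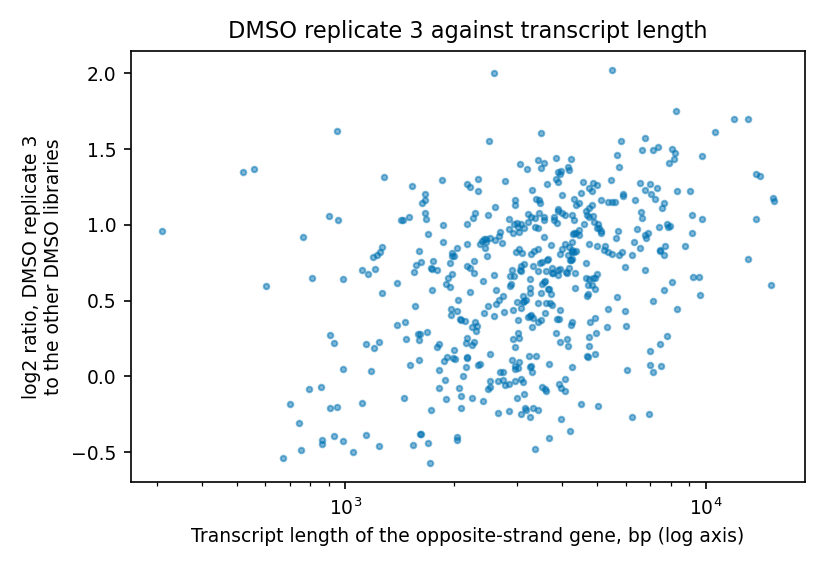
Log2 ratio of counts in DMSO replicate 3 to the mean of the other DMSO libraries, against transcript length of the opposite-strand gene in bp (log axis), with 1 point per gene for 501 genes. The ratio rises with length (Spearman rho = 0.370).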

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

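The sums by opposite-strand gene and their alternatives were chosen only after the data were seen; the others were fixed before. Of 40 named genes past the threshold by the table's names, 29 kept their call in every alternative run on them, libraries left out included. Of 33 opposite-strand genes, 29 did. These tallies share counts, as for Ube2c and the sum opposite Tnnc2. Samples with the same replicate number showed no shared deviation (correlations of deviations -0.011, 0.023 and 0.018), which does not settle whether they were paired. With a replicate block there were 197 genes higher, 245 lower and 254 at least 2-fold, with 102 and 139 opposite-strand genes and 0 and 3 lists; the calls of Nr1d1 (adjusted p = 0.0533) and Igf2r (0.0514) ended and Rpl32 passed (0.0491). At an adjusted p of 0.01 there were 80 higher and 128 lower, and 43 and 75 opposite-strand genes, by construction. Requiring a mean count of at least 50 left 111 genes changed at least 2-fold, as fewer were tested. With no filter, 129 genes were higher and 303 lower. Lists by the table's names went from 0 to 4 with fry. Lists by opposite-strand gene went from 3 to 0 with an estimated correlation, 1 with at least 5 tested members, as fewer lists were tested, and 1 with no filter, where muscle and lysosome ended (adjusted p = 0.0824 each). Leaving out 1 library gave 93 to 259 genes higher, 143 to 359 lower, 184 to 288 at least 2-fold, 59 to 162 and 89 to 209 opposite-strand genes, and 2 to 4 lists. Where no cause is named here, the cause was not tested.

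The values whose direction turned were not past the threshold in the edgeR or camera test. Cox6c stood at 0.0146 with DESeq2 size factors, 0.0216 with upper-quartile scaling, 0.0146 with the DESeq2 test and -0.151 to 0.104 with 1 library left out. With no filter, Atp2a1 was at -0.00031, Rpl18 at -0.0355 and Runx2 at -0.0900. With 1 library left out, Atp2a1 ranged from -0.113 to 0.422, Hsp90b1 from -0.338 to 0.0810, Rpl18 from -0.0930 to 0.184, Runx2 from -0.205 to 0.116, and by opposite-strand gene Rfc4 from -0.386 to 0.0701 and Sqstm1 from -0.161 to 0.333. Lists that turned are given by adjusted p: with fry, unfolded protein response 0.998 and SRF targets 0.578; with no filter, unfolded protein response 0.672, mitosis 0.452, SRF targets 0.962 and collagen 0.997; with the replicate block, muscle 0.959 and mitosis 0.959. With 1 library left out these p-values ranged from 0.804 to 1.000 for the respiratory chain, muscle and unfolded protein response, 0.831 to 1.000 for mitosis, 0.831 to 0.940 for glycolysis and, by opposite-strand gene, 0.447 to 0.984 for the proteasome. Small changes can be missed: in simulated data of this comparison 48.4% of 2-fold changes were recovered. Depth was not varied in that simulation, so its part in this cannot be told. The cause of these turns was not tested.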

Other observations

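The sums by opposite-strand gene, the tests for shifted identifiers and for both explanations of DMSO replicate 3, the simulation and the second set of pairs, the comparison of list members under scaling, the counts of splits and the genes named in the next paragraph were chosen only after the result was seen; the others were written before.

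Sums opposite further list members also moved. Opposite Fabp3, the heart and muscle fatty acid binding protein, the sum rose by 3.81 ± 0.52 (log2, SE) from 9.26 ± 8.71 CPM (SD, n = 3). Opposite Msc, a repressor of myogenesis, it was 4.26-fold lower, and opposite the transcription factor gene Cebpb 2.13-fold lower. Tubulin genes parted, with Tuba4a 2.57-fold higher and Tubb4b 1.69-fold lower. Among actin-linked genes Vcl, vinculin, was 1.32-fold higher and Zyx 2.71-fold lower. All of these had adjusted p under 0.05 in edgeR.

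Counts lay in genes with opposite-strand exons in 91.82% of cases, against at most 42.5% when identifiers were shuffled 10000 times, which argues against identifiers shifted against their counts; libraries that are shallow but counted on the right strand are argued against by the median percentile of 65.57 for 54 proteasome and respiratory chain genes, under the bound of 80, with 93.3 for the 7 table genes opposite them. For counting of a strand-marking library on the opposite strand, pairs of genes sharing an opposite-strand gene were tested. The explanation was to give an r over 0.5 and above every shuffled pairing. A value inside the shuffled range was written beforehand as against it. Over 43 pairs r was 0.2103, inside that range (highest 0.525). A second set of 31 pairs followed the rule of the sums, with a protein-coding neighbour and at least 50 bp. It gave 0.416, which few shuffled pairings reached in size (permutation p = 0.021), though it lay under the highest of 10000 (0.603). Lying under the highest of 10000 shufflings says little against the explanation, and this set was chosen after the first result was seen. In simulated sets of the 43 pairs in which each pair shared 1 change, r lay between 0.350 and 0.766 (2.5th percentile and the one as far from the top), above the observed value, but only 73.23% exceeded the bound, so the bound was set too high for a miss to exclude the explanation, and the simulated range rests on an assumed spread of changes. Counting throughout on the strand of the named gene is argued against by the low counts of abundant transcripts. Mean counts were 8.17 for Actb and 0.167 for Rpl3. The 37 proteasome and respiratory chain genes without opposite-strand exons had a median total of 4 counts over 6 libraries. Among mitochondrial genes, mt-Co2 and mt-Co3 had 0 counts, while mt-Nd6 of the light strand had a mean count of 38838. This too argues against counting throughout on the strand of the named gene. Whether the reads were counted on the opposite strand in part or throughout cannot be told from these tables. No biological explanation was tested, and how much of the concentration opposite-strand counting accounts for stays open.

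DMSO replicate 3 differed from the other DMSO libraries. Deeper counting alone is argued against by the relation of its log2 ratio to the transcript length of the opposite-strand gene (rho = 0.3697), since depth would act on all lengths alike. The relation to the exon length of the table's own gene was weaker and of the other sign (rho = -0.1057), so length-dependent recovery of the RNA is a candidate explanation. With the same lengths DMSO replicate 2 over replicate 1 gave rho = 0.0732 and the compound libraries over both gave rho = 0.158, so a length relation was not confined to DMSO replicate 3. A difference between cultures stays open and was not tested.

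Sums opposite mitosis genes were lower and those opposite lysosome genes higher. A length or GC trend between the full groups is argued against, since log2 changes over 1034 sums hardly followed length (rho = -0.0149) or GC (rho = -0.0826). Removing so small a trend tests nothing more (gap between the list medians 2.57 before and 2.6309 after, log2). These changes include DMSO replicate 3, which itself followed length. Against DMSO replicates 1 and 2 alone the compound libraries gave rho = 0.158 with length, and the gap was not tested there. Scaling is argued against as the source of the gap, since a shift common to all sums leaves the gap between the lists as it is. The highest mitosis member plus its SE lay at -0.89 and the lowest lysosome member minus its SE at -0.27. The gap does not settle the sign of either list. The medians kept opposite signs under 3 scalings (mitosis at most -1.7886). As these moved them by at most 0.02, no sign could have turned. Both lists hold 3 or 4 genes, and the call ended with an estimated correlation (adjusted p = 0.161). An effect of the compound on these transcripts stays open, as the sums are not shown to measure them and no recount with the other strand setting was made.

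With 10 splits of 6 libraries into 3 and 3, a share under 0.05 cannot be reached. The real grouping gave 438 genes, 262 genes at least 2-fold and 238 opposite-strand genes, and the highest of the other splits gave 0 for each, so 1 split of 10 was as large. For lists by opposite-strand gene the real grouping gave 3 and the highest of the others 4, and 3 of 10 splits gave as many.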
